A study of Mus musculus with 2 samples.

How the data were processed

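Tumours of Myc-CaP cells, wild type (WT) or IRE1α knockout (KO, the line the submitters call KO2), were profiled by 3′ single-cell RNA sequencing with the GEXSCOPE kit of Singleron, in which cells are isolated on a chip and their mRNA is tagged with a cell barcode and a UMI. Per the labels' protocols, 6 tumours of each group were pooled, dissociated with enzymes, filtered, freed of red blood cells and loaded as 1 library, and libraries were sequenced on a NovaSeq instrument. Each group therefore had 1 sample. The deposited matrices held whole-number UMI counts per gene and barcode, not normalized, per the file headers and the values. The genome build was GRCm38, per the submitters' processing notes, and the aligner and the annotation were not given in the sources used here.

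The matrices listed all barcodes, not cells alone. Barcodes under 100 UMIs numbered 1574503 in the WT and 1596759 in the KO library and held 10.5% and 7.25% of UMIs, and their summed counts gave each library's free-RNA profile. For the high-UMI set, barcodes were ranked by total UMI, log10 totals at 200 evenly spaced log10 ranks from rank 100 were smoothed over 11 points, and the steepest point, with a floor of 500, gave the UMI minimum, 5804 in the WT and 7589 in the KO library. A cell also needed 200 genes and at most 20% mitochondrial UMIs. These steps took 6999 and 4781 barcodes to 6964 and 4734 cells. Doublets were called with scrublet through scanpy at an expected rate of 0.06. The caller marked 3 WT and 3 KO cells. In the WT library that was under 0.5% of over 5000 cells, so it was judged not to have worked and no WT cell was removed, while the 3 KO calls were removed, which left 4731 cells. Doublets therefore remain in these cells, perhaps most of all among those with many UMIs, which was not tested.

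At these minimums only cancer-like, macrophage-like, fibroblast-like and endothelial cell-like clusters could be named. A low-UMI set was therefore added after the data were seen. Barcodes from 500 UMIs up to the library's own UMI minimum were tested against the free-RNA profile with 10000 Monte Carlo draws. They were kept at a Benjamini-Hochberg FDR of 0.001, and barcodes at or above the minimum were kept untested. Together these were 12366 WT and 8638 KO barcodes, and 10903 and 7298 cells after the gene and mitochondrial limits and the removal of 125 and 37 doublet calls. Cells outside cancer-like clusters were clustered again there, and T and NK cells once more on 15 principal components.

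Cells of both libraries were clustered together without integration, on counts per 10000, log-transformed, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Mitochondrial, ribosomal protein, haemoglobin and T cell receptor variable genes were left out of the variable genes. A cluster was named from markers fixed before the data were examined. The thresholds were set after seeing the data and were at least 3 markers detected in 25% of cells, with a median log2 score of at least 3 over the other cells and 5 CPM added. Cancer-like cells were named by epithelial markers in clusters without a score of 1.5 for any other class. Clusters left without a name held 0.962% of WT and 0.888% of KO cells in the high-UMI set and 11.7% and 16.7% in the low-UMI set. Among T and NK cells, subclusters were named from 3 markers at least 1.5-fold above the other T and NK cells. Names such as macrophage-like rest on these rebuilt clusters. Krt18 was close to absent from these matrices, with 0.269 and 0.480 CPM in cancer-like cells, and was not relied on.

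Expression was compared by summing raw UMIs per library and class and scaling to counts per 10⁶ UMIs (CPM). The log2 ratio is KO over WT with 0.5 counts added to each sum, and folds are the same ratio. Intervals at 95% are exact, Poisson for sums and their ratios and Clopper-Pearson for shares, with the Newcombe interval for a difference of shares. They cover counting error only. With 1 library per group there was no test across samples and no p-value. A class was compared with at least 30 cells in each library, so neutrophil-like cells, with 12 KO cells, were not compared and the immunosuppressive neutrophil list was not computed. A list member was measured with at least 20 UMIs over both libraries. The list's median log2 ratio was placed among 10000 random lists of the same size matched on mean CPM in 20 bins, which describes these libraries. Members at least 1.5-fold higher or lower were counted by size alone.

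The gene lists covered XBP1s and ER-associated degradation, ATF6 and ER chaperones, PERK with ATF4 and CHOP, RIDD substrates, type I interferon and interferon gamma responses, MHC class I and II presentation, S phase, G2 and M phase, MYC targets, hypoxia and glycolysis, epithelial-mesenchymal transition, cholesterol and fatty acid synthesis, chemokines and cytokines, tumour-associated and inflammatory macrophages, cytotoxic lymphocytes, T cell exhaustion and checkpoint, naive and memory T cells, extracellular matrix, endothelial activation and angiogenesis, and immediate early and dissociation stress. Some genes stand in more than 1 list, Tapbp in the RIDD and MHC class I lists, Ctss and Cxcl10 among others. Lists, markers, the UMI minimum rule and the rule for named genes were fixed before the data were examined.

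The named genes were always Ern1 and Xbp1. In cancer-like cells they were the 12 highest and 12 lowest log2 ratios among genes with at least 50 UMIs over both libraries, 10 CPM in the higher one, a 2-fold ratio and an interval that held no value of no difference. In other classes of the plan with at least 100 cells per library, which were macrophage-like cells alone, the rule took 4 each way with at least 30 UMIs. Lists in monocyte-like and dendritic cell-like cells were compared outside the plan. Left out were unnamed gene models (Gm with digits, names ending in Rik, clone names), mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, and genes whose CPM in the class was below that of the other cells of the library. From each list up to 4 members with at least 50 UMIs were named, the 2 largest and 2 smallest ratios, and these were named also where the class had less of the gene than other cells. Some genes that met these rules, and 1 list, are not reported. Where a library had 0 counts, the fold is a lower bound from a floor of 3 counts per library. Of 53715 gene identifiers, 53620 were found in the reference name table and 52029 had the same symbol. Symbols repeated 120 times, and for a repeated symbol a list used the first entry. List symbols absent from the gene table were not measured.

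Free RNA per class was estimated from genes of another class, Krt8, Cldn3, Cldn7 and Spint2 in non-cancer classes and macrophage genes in cancer-like cells. Krt8 stood at 416.1 and 388.7 CPM in cancer-like and 34.8 and 36.4 CPM in macrophage-like cells. To compare depths, each cell of the high-UMI set was thinned to 1000 UMIs, which left out 0 cells in either library. The guide was matched to GENCODE M21 transcripts on GRCm38.

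Alternatives fixed in advance were a UMI minimum of 1000 in both libraries, a minimum at 10% of the 99th percentile of the 3000 highest barcodes, a mitochondrial limit of 10%, no doublet removal, naming of each cell by its own marker score, Leiden resolutions 0.5 and 2, thinning, scaling to the median gene, and list minimums of 1 and 100 UMIs. Added after seeing the data were the low-UMI set and its own alternatives, the higher of both minimums for both libraries, subtraction of free RNA, removal of clusters with over 90% of cells from 1 library, and removal of the cell with most UMIs.

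The method was tested on simulated data drawn from the summed counts, with 200 genes changed by known folds. For cancer-like cells, with 17815 genes, 95.7% of unchanged genes had an interval that held no difference. Of genes changed 4-fold and 8-fold, 100% met the naming rule, of those changed 2-fold 52.0% and of those changed 1.5-fold 0%. There, 0 of 17615 unchanged genes met it. For macrophage-like cells, with 9777 genes, the interval held no difference for 96.4%, the rule took 100% of genes changed 4-fold and 8-fold, 40.0% of those changed 2-fold and 8% of those changed 1.5-fold, and 46 of 9577 unchanged genes. Of 200 random lists, 12 in the cancer-like and 4 in the macrophage-like simulation fell outside the central 95%, and 20 of 20 shifted lists were found in each. Simulated free-RNA barcodes passed p at or below 0.05 in 5.0% of 200 draws, and 100% of 200 T cell-like barcodes passed 0.001. The first came from the test's own free-RNA profile. The second came from the summed WT T cell-like cells of the low-UMI set, which this test had helped to keep. With fewer Monte Carlo draws and no FDR, they check the calculation and not how well real barcodes are sorted. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.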

Results

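The series compared tumours grown from Myc-CaP, a mouse prostate cancer cell line driven by overexpressed Myc, with tumours of a derived line in which IRE1α had been knocked out. IRE1α, encoded by Ern1, is a sensor of unfolded protein in the endoplasmic reticulum (ER). Its RNase domain splices Xbp1 mRNA into the form that encodes the active transcription factor XBP1s, and it also degrades other mRNAs, a process called RIDD. The question was how loss of IRE1α in the tumour cells goes with the state of those cells and of the immune and stromal cells around them. Tumours were dissociated and sequenced as single cells with 3′ tags and unique molecular identifiers (UMIs). Each group was 1 library made from a pool of 6 tumours, so the difference between groups had no replicate check, and every interval given here is a 95% interval that covers counting error only.

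The WT library held 257083941 UMIs over 1753677 barcodes and the KO library 227330666 UMIs over 1721161 barcodes, each against 53715 genes. Cells were taken first at a UMI minimum set by each library's own rank curve, 5804 in the WT library and 7589 in the KO library. This high-UMI set held 6964 WT cells with a median of 20987 UMIs and 4731 KO cells with a median of 29691 UMIs. Cancer-like cells, named from epithelial markers such as Krt8, Cldn3 and Cldn7, numbered 6414 in the WT library and 4541 in the KO library. Macrophage-like cells numbered 340 and 111. A low-UMI set, defined after the data were seen, also kept smaller cells below these minimums whose RNA differed from the free RNA between cells. It held 10903 cells in the WT library and 7298 in the KO library and resolved lymphocytes, dendritic cells, monocytes and neutrophils.

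The guide RNA of the knockout matched 1 gene among 141767 annotated transcripts, Ern1 (ENSMUSG00000020715, chromosome 11, 106394650 to 106487852 on the minus strand, GRCm38). Its 20-base target lay in coding sequence of exon 2 of 22 of the longest transcript, at 106458942 to 106458961, followed by the PAM AGG. That site lies 6679 bases from the 3′ end of the longest transcript but 386 and 375 bases from the end of 2 short ones. Counts per gene do not show the edited bases, so the level of Ern1 was not used to check the edit or the labels. In cancer-like cells Ern1 stood at 25.1 CPM in the WT library (3732 UMIs) and 26.7 CPM in the KO library (3897 UMIs), a log2 ratio of 0.09 (0.03 to 0.16). With each cell thinned to 1000 UMIs, which kept a small part of these UMIs, the log2 ratio was 0.36, given without an interval. A UMI of Ern1 was found in 37.5% of WT and 48.3% of KO cancer-like cells, at median depths of 21889.5 and 30179 UMIs, and in 10.9% and 17.1% of macrophage-like cells at 7930 and 10818 UMIs. Xbp1, the mRNA that IRE1α splices, was lower in KO cancer-like cells by 1.37-fold (1.344 to 1.397), at 120.4 CPM against 164.9 CPM. In macrophage-like cells, which are taken to be unedited host cells, Ern1 was at 13.8 CPM in the WT and 16.8 CPM in the KO library, and Xbp1 at 163.4 and 146.5 CPM.

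Cancer-like cells of the KO library had lower levels of the genes that XBP1s controls in the secretory pathway and higher levels of interferon-stimulated genes. Of 28 measured genes of XBP1s and ER-associated degradation, 18 were at least 1.5-fold lower in the KO library and 0 were higher, with a median log2 ratio of -0.74. Of 33 measured genes of the type I interferon response, 21 were at least 1.5-fold higher and 1 lower, with a median of 0.76. Saa1, Fga and Fgb were among the single genes with the lowest ratios. The median log2 ratio of all genes in this class was 0.03.

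Within the XBP1s list, Sec24d, a component of the vesicle coat that carries cargo out of the ER, was lower by 3.66-fold (3.44 to 3.90). Serp1, which stabilises new membrane proteins at the translocon, was lower by 2.76-fold (2.72 to 2.80). At the other end of the list, Kdelr3, a receptor that returns proteins to the ER, was lower by 1.08-fold, and Arfgap3, a regulator of Golgi transport, was higher by 1.01-fold, with an interval that held no difference. The list's median lay at percentile 0 of 10000 random lists matched on expression, which describes these 2 libraries and is no test between conditions. The ATF6 and ER chaperone list had a median of -0.27 over 13 genes and also lay at percentile 0. Its lowest members were Creld2, an ER stress-induced isomerase, lower by 2.04-fold, and Atf6 itself, lower by 1.45-fold. The abundant chaperones Hsp90b1 and Calr were higher by 1.06-fold and 1.12-fold. Genes downstream of PERK, another ER stress sensor that acts through ATF4 and CHOP, had a median of 0.19 over 23 genes, at percentile 99.9, with 6 higher and 1 lower by at least 1.5-fold. Chac1, which degrades glutathione, was higher by 2.23-fold and Trib3, a pseudokinase induced by CHOP, by 2.02-fold. A cancer-like cluster whose leading genes included Ddit3, Chac1 and Atf3, cluster 4, held 132 WT and 905 KO cells. This list was not compared within clusters, so the rise may not be general to KO cancer-like cells. Nupr1, a stress-induced chromatin protein, was lower by 2.72-fold and Slc7a11, the cystine importer, by 1.37-fold.

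Known RIDD substrates went both ways. Among 10 measured, 5 were lower and 1 was higher by at least 1.5-fold, and the median was -0.28 at percentile 0.38. Bloc1s1, the best known substrate, was higher by 1.29-fold (1.187 to 1.404) and Tapbp, which loads peptides on MHC class I, by 1.56-fold. Sparc, a matrix protein, was lower by 1.73-fold, and Col6a1 by 2.38-fold at 76 and 31 UMIs, though its log2 ratio was 1.24 with each cell thinned to 1000 UMIs. Thinning kept few of these UMIs, since median depths were 21889.5 and 30179 UMIs, so the thinned value is uncertain and has no interval. Only 2 of the 10 had CPM in cancer-like cells at or above that in the other cells, and free RNA was not tested for this list.

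**Figure D1:**
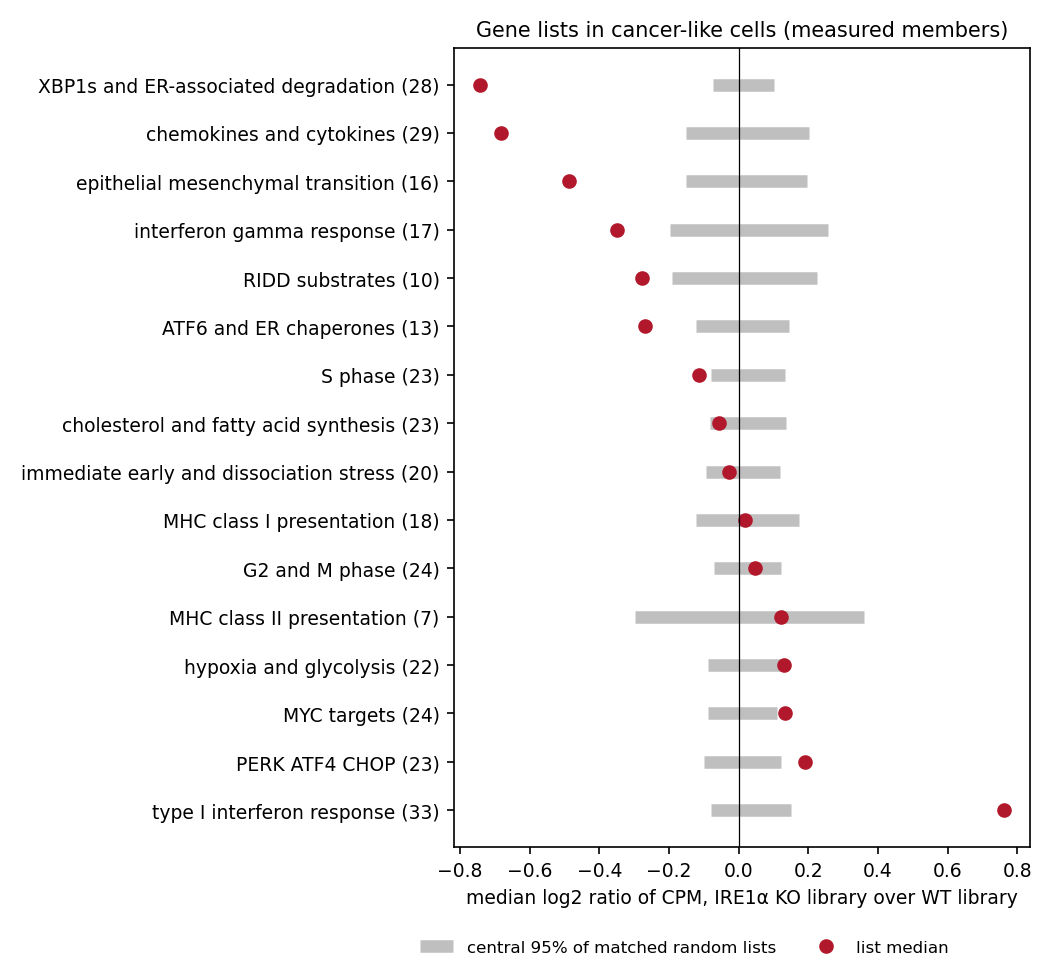
Median log2 ratio of CPM, KO library over WT library, for each reported gene list in cancer-like cells (red points), with the central 95% of matched random lists (grey bars) and the number of measured members in parentheses. The XBP1s list sits lowest at -0.74 and the type I interferon list highest at 0.76.

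Interferon-stimulated genes in cancer-like cells were led by Oas3, which makes the activator of RNase L, higher in the KO library by 3.17-fold (2.80 to 3.59), and Ifi27l2a, higher by 2.96-fold (2.85 to 3.07). The antiviral GTPase Mx1 was lower by 1.75-fold at 61 and 34 UMIs, and Ifih1, the RNA sensor MDA5, by 1.30-fold with an interval that held no difference. The list's median was at percentile 100, and 0 of its members had CPM at or above that of the other cells. Genes of the interferon gamma response did not follow it, with a median of -0.35 over 17 genes, 4 higher and 7 lower. Iigp1 was lower by 4.52-fold and Cxcl10, a chemokine for T cells, by 3.35-fold, with 25.5% and 35.8% of their WT UMIs in 1 cell, while the interferon-inducible GTPases Irgm2 and Tgtp2 were higher by 1.74-fold and 1.62-fold. This median rested on genes with few UMIs. It was 0.02 among members with at least 100 UMIs and 0.07 with cells thinned to 1000 UMIs, and after subtraction of free RNA it was -0.184, at the lower end of the random lists at -0.183. The MHC class I list had a median of 0.02 over 18 genes at percentile 43.6. Tapbp and the peptide trimming enzyme Erap1 were higher by 1.56-fold and 1.26-fold, and the nonclassical genes H2-M3 and H2-Q6 were lower by 2.72-fold and 1.35-fold, the second with an interval that held no difference and with reads that related H2-Q genes can share. MHC class II genes had a median of 0.12 over 7 genes at percentile 67.6. H2-DMb1 was higher by 1.97-fold and H2-DMb2 by 1.83-fold, and Ctss and Cd74 were lower by 1.74-fold and 1.14-fold.

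The 12 genes with the largest ratios toward the KO library began with Rhox2h, an X-linked homeobox gene of the reproductive tract, at 0.450 CPM in the WT and 17.9 CPM in the KO library, 39.4-fold higher (31.1 to 51.4). Cyp2f2, a cytochrome P450, was higher by 5.05-fold, Xlr by 5.02-fold and Stra6, the receptor for retinol-binding protein, by 4.13-fold. Next came Nedd4l, a ubiquitin ligase, at 3.85-fold, the estrogen sulfotransferase Sult1e1 at 3.71-fold and Clca1 at 3.21-fold. Apol9a and Apol9b, interferon-inducible apolipoprotein L genes, were higher by 3.33-fold and 2.84-fold, and the carbonic anhydrase Car14 by 2.84-fold. Fam89a was the most abundant of the 12, at 189.5 and 535.8 CPM, 2.83-fold higher, and Cyp2c70 closed the group at 2.71-fold. Rhox2h, Xlr, Apol9a, Apol9b and Saa1 each have close paralogs that can share reads, so their values are uncertain. Rhox2h, Sult1e1, Clca1, Cyp2c70, Apol9a and Apol9b were among the leading genes of cluster 2, with 272 WT and 971 KO cells. Stra6 was among those of cluster 4, with 132 and 905. The make-up of clusters can therefore add to these ratios, and ratios of single genes within clusters were not compared.

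On the opposite side, Saa1, an acute-phase apolipoprotein, was lower in the KO library by 10.5-fold (9.97 to 11.1), at 10.9 CPM against 114.6 CPM. Spinkl, a secreted protease inhibitor, was lower by 8.98-fold, Mapk13, the p38δ kinase, by 6.14-fold and Fmo1, a flavin monooxygenase, by 5.11-fold. Fgb, the fibrinogen beta chain, was among the most abundant transcripts of these cells and stood at 3264 CPM in the WT and 805.5 CPM in the KO library, 4.05-fold lower (4.03 to 4.08), with Fga lower by 3.89-fold. Pip, a secretory protein, was lower by 4.15-fold, although 1 WT cell held 14.1% of its UMIs. After these came Asb4 at 3.73-fold, the sulfate transporter Slc13a4 at 3.57-fold, the mitochondrial arginase Arg2 at 3.45-fold and Elobl at 3.44-fold. Clusters 10 and 12, with 409 and 203 WT cells against 3 and 2 KO cells, were led by genes that included Fmo1, Saa1, Fgb and Fga and may be particular to that library. Each was named cancer-like from 4 epithelial markers, with a median log2 marker score of 0 over the cells of other named classes. Their cells count in the WT sums, so they can add to the ratios of these genes. The largest cancer-like clusters of the WT library were 0, 3 and 1, and those of the KO library 2 and 4.

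Proliferation genes were at similar levels in the cancer-like cells of both libraries. The S phase list had a median of -0.12 over 23 genes at percentile 0.51, with 0 members 1.5-fold apart. Cdc45 and Cdc6, which load and start the replicative helicase, were lower by 1.46-fold and 1.33-fold, and the helicase subunits Mcm6 and Mcm7 were higher by 1.06-fold and 1.10-fold, although Mcm6 had a log2 ratio of -0.18 with cells thinned to 1000 UMIs. The G2 and M phase list had a median of 0.05 over 24 genes at percentile 64.7. Cenpe and Birc5, of the mitotic spindle, were lower by 1.31-fold and 1.25-fold, and Ccnb2, a mitotic cyclin, and Cenpa were higher by 1.29-fold and 1.22-fold. MYC targets had a median of 0.13 over 24 genes at percentile 99.1, none 1.5-fold apart. The ribosome biogenesis genes Rrp9 and Gnl3 were each higher by 1.25-fold, and Npm1 and Cad lower by 1.20-fold and 1.17-fold.

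Hypoxia and glycolysis genes had a median of 0.13 over 22 genes at percentile 98.0. Their outlying member was Adm, the vasodilator adrenomedullin, at 7.18 CPM in the WT and 0.535 CPM in the KO library, 13.3-fold lower (10.7 to 17.1). The glucose transporter Slc2a1 was higher by 1.49-fold, the glycolytic kinase Pfkp by 1.38-fold, and P4ha2 was lower by 1.14-fold. Cholesterol and fatty acid synthesis genes had a median of -0.06 over 23 genes at percentile 5.80, with the desaturases Scd1 and Fads1 higher by 1.74-fold and 1.23-fold and Insig1 and Elovl6 lower by 1.37-fold and 1.32-fold. The immediate early and dissociation stress list was at -0.03 over 20 genes, percentile 19.4. Ier3 and Egr1 were lower by 1.32-fold and 1.29-fold, and Nr4a1 and Hspa1b higher by 1.29-fold and 1.21-fold.

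Chemokine genes and genes of epithelial-mesenchymal transition had lower summed CPM in KO cancer-like cells, at low levels to which free RNA can contribute. The chemokine and cytokine list had a median of -0.68 over 29 genes at percentile 0, with 15 lower and 1 higher by at least 1.5-fold. Il1b was lower by 3.09-fold at 140 and 44 UMIs and Ccl8, a monocyte chemokine, by 2.78-fold, while Cx3cl1 was higher by 1.69-fold and Il10 by 1.30-fold with an interval that held no difference. The epithelial-mesenchymal transition list had a median of -0.49 over 16 genes at percentile 0, with 3 higher and 7 lower. Tnc and Mmp14, of matrix and matrix breakdown, were lower by 3.94-fold and 3.44-fold at 106 and 89 WT UMIs, and the transcription factor Zeb1 and the integrin Itga5 were higher by 1.85-fold and 1.76-fold. Just 3 of the 29 and 0 of the 16 had CPM at or above that of the other cells. C1qa, a macrophage gene that cancer cells lack, moved the same way, with a UMI in 10.3% of WT and 6.06% of KO cancer-like cells (4.99 and 2.11 CPM) against 92.4% and 86.5% of macrophage-like cells. So did Lyz2, another macrophage gene, at 21.8 CPM in WT and 7.62 CPM in KO cancer-like cells. Free RNA was estimated at 4.26% and 3.98% of the UMIs of cancer-like cells. These estimates give its amount and not which genes it held, so free RNA stays open as a source of these differences.

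Macrophage-like cells of the KO library carried higher interferon-stimulated genes. No monocyte-like class was named by clusters in the high-UMI set, while per-cell naming gave 14 WT and 12 KO monocyte-like cells there. The macrophage-like class of that set may therefore hold monocytes. Of 34 type I interferon genes, 20 were at least 1.5-fold higher and 0 lower, with a median of 0.63 at percentile 100. Ifi44 was higher by 3.65-fold (2.77 to 4.87) and the RNA helicase Ddx60 by 2.11-fold, while Ifit1 was lower by 1.17-fold and Rsad2 differed by 1.00-fold, both with intervals that held no difference. The MHC class I list had a median of 0.32 over 18 genes at percentile 100, 2 of them at least 1.5-fold higher and 0 lower, with Tap1, the peptide transporter, higher by 1.72-fold and H2-Q7 by 1.46-fold. Psme2 and Erap1 differed by 1.05-fold and 1.00-fold, with intervals that held no difference. Interferon gamma genes had a median of 0.09 over 19 genes at percentile 71.9. Cxcl11 was higher by 3.37-fold and Cxcl9 by 2.44-fold, with 61.8% of the KO UMIs of Cxcl9 in 1 cell, and Cxcl10 and Gbp3 were lower by 1.95-fold and 1.16-fold, the second with an interval that held no difference. MHC class II genes were at -0.01 over 8 genes, percentile 38.3. H2-DMb2 and H2-DMa were lower by 1.64-fold and 1.28-fold, and Ctss was higher by 1.08-fold and H2-Eb1 by 1.29-fold, the latter with an interval that held no difference. With low-UMI cells kept the direction turned for Cxcl9, at a log2 ratio of -1.12, and for H2-Eb1, at -0.997.

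The largest macrophage ratios toward the KO library began with the gene ENSMUSG00000029378, 9.20-fold higher (4.58 to 22.5) at 9 and 40 UMIs, the latter in 2 KO cells, 1 of which held 75.0% of them. The gene table of the data calls it Mcub, a symbol it gives to another gene too, and the reference name table calls it Areg, the EGFR ligand amphiregulin. Slfn4, an interferon-inducible gene of monocytes, was higher by 6.31-fold (5.29 to 7.58), Rnase2a by 5.61-fold with 88.7% of KO UMIs in 1 cell, and Plac8 by 4.87-fold. The lowest were receptors of the Cd209 family, with 0 UMIs in the KO library. Cd209f was at least 28.1-fold lower, with 182 UMIs in 9 WT cells, Cd209d at least 21.2-fold and Cd209a at least 8.50-fold with 47.3% of WT UMIs in 1 cell, and reads can be shared among them. Cd209d had a log2 ratio of 0.03 with low-UMI cells kept. Ifna2 was at least 9.11-fold lower, from 59 UMIs in 2 WT cells, 1 of which held 84.7% of them. Folds written as "at least" used a floor of 3 counts per library.

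Tumour-associated macrophage genes had a median of -0.09 over 30 genes at percentile 1.24, with 4 higher and 5 lower, and 0.012 with per-cell naming. The haemoglobin scavenger receptor Cd163 was lower by 14.5-fold (5.61 to 82.9) at 109 and 3 UMIs, and Lyve1, a mark of resident perivascular macrophages, by 4.10-fold. Gpnmb, a lysosomal glycoprotein, was higher by 3.56-fold, with 34.6% of KO UMIs in 1 cell. Chemokine genes had a median of 0.12 over 26 genes at percentile 95.7. Il1b and Il1a were lower by 3.26-fold and 2.07-fold, Tgfb3 was higher by 3.21-fold, and Ccl24 by 2.78-fold with 96.4% of KO UMIs in 1 cell. The inflammatory macrophage list had a median of 0.35 over 15 genes in the high-UMI set and -0.34 in the low-UMI set, so its direction depended on which cells were counted. Within the low-UMI set it also turned with naming and clustering, to 0.21 with per-cell naming and 0.17 at resolution 0.5. Ccl5 was higher by 1.77-fold in the high-UMI set, with 34.5% of KO UMIs in 1 cell. The hypoxia list was at 0.02 over 22 genes, percentile 51.7, with Hilpda lower by 1.37-fold, Ankrd37 by 1.31-fold (a log2 ratio of 0.03 with cells thinned to 1000 UMIs), Pfkp higher by 1.34-fold, and P4ha2 by 1.35-fold with an interval that held no difference. Immediate early genes were at -0.17 over 20 genes, percentile 0.050, with Nr4a1 and Fosb lower by 2.16-fold and 1.60-fold, Hspa1b higher by 1.38-fold with 44.3% of KO UMIs in 1 cell, and Hsph1 by 1.12-fold with an interval that held no difference. Both turned once low-UMI cells were kept, to log2 ratios of -0.25 and -0.75. Free RNA was estimated at 8.02% of WT and 9.75% of KO UMIs in this class.

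In the low-UMI set, with 934 and 226 macrophage-like cells, the interferon and MHC class I medians were 0.50 and 0.26, both at percentile 100, with 11 of 34 interferon genes at least 1.5-fold higher, and the tumour-associated macrophage median was -0.16 at percentile 0. Interferon gamma, MHC class II, hypoxia, chemokine and immediate early lists had medians of -0.06, -0.06, 0.05, 0.04 and -0.21. Genes named there were Slfn4 at 4.24-fold, the VEGF receptor Flt1 at 3.71-fold and the leukotriene receptor Ltb4r1 at 3.69-fold higher, the last with 36.7% of KO UMIs in 1 cell. Lower were Chp2 by 6.84-fold (2.21 to 72.0) at 46 and 2 UMIs, Ifna2 by 5.94-fold with 89.3% of WT UMIs in 1 cell, Fxyd2 by 5.68-fold and the eosinophil chemokine Ccl24 by 5.47-fold, against its higher value in the high-UMI set. Cd209f, Folr2 and Lyve1 led 1 of the 4 macrophage-like clusters of this set, with 93 of 934 WT and 14 of 226 KO cells. The make-up of the class can therefore add to their ratios. Ratios within clusters were not compared, so how much it adds was not tested.

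Immune-like cells made up a smaller share of the KO library. In the high-UMI set they were 4.88% of WT cells (340 of 6964, 4.39 to 5.42) and 2.35% of KO cells (111 of 4731, 1.93 to 2.82), a difference of -2.54 percentage points (-3.20 to -1.86), and all came from 1 macrophage-like cluster. Fibroblast-like cells were 1.84% of WT and 0.634% of KO cells, a difference of -1.20 points (-1.60 to -0.808). Of these 128 and 30 cells, 77 and 20 were named mural cells at resolution 2, which left a fibroblast-like difference of -0.521 points, and with 7589 UMIs in both libraries it was -0.753 points. Endothelial cell-like cells, 15 and 7 in number, were 0.215% and 0.148%, with an interval of the difference from -0.227 to 0.111. Cancer-like cells took 92.1% and 96.0%, and unnamed clusters 0.962% and 0.888%. The UMI minimum was 5804 for WT and 7589 for KO cells, and immune-like cells had fewer UMIs than cancer-like cells, with medians of 7930 and 10818, so the gap in minimums bears on these shares. With 7589 UMIs required in both libraries the immune-like difference was -0.616 points (-1.21 to -0.00565), and with 1000 UMIs in both it was -4.22 points. Other immune cells were present in this set but not counted. Cluster 14, with 67 WT and 42 KO cells and no name, was led by Igha, Jchain, H2-Aa and Cd74, and at resolution 2 a cluster of 17 and 12 cells was named cDC1.

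With low-UMI cells kept, the immune-like cells of the KO library held relatively fewer macrophages and more NK cells. Immune-like cells were 14.2% of 10903 WT cells and 8.14% of 7298 KO cells, a difference of -6.11 points (-7.02 to -5.20). Macrophage-like cells were 8.57% of all WT and 3.10% of all KO cells, whereas monocyte-like cells, their precursors, were 2.48% and 2.22%. Among immune-like cells they went in opposite directions, macrophage-like cells from 934 of 1554 in the WT to 226 of 594 in the KO library and monocyte-like cells from 270 to 162 of these, a larger part. Together they were 77.5% and 65.3% of immune-like cells, a difference of -12.2 points (-16.6 to -7.87). Across alternatives this ran from -18.0 points, with each cell of this set named by its own score, to -4.78 points (-11.4 to 0.0572) in the high-UMI set at resolution 2, where the interval held 0. NK cell-like cells were 3.28% (51 cells) and 9.60% (57 cells), 6.31 points apart (3.97 to 9.06), and per-cell naming gave 3.78 points here and 1.34 in the high-UMI set. Dendritic cell-like cells were 7.27% and 12.8%, 5.52 points apart (2.70 to 8.68), a class that took in plasma cells. Their difference was 1.79 points at resolution 0.5, 12.2 points with per-cell naming and 1.77 points (-2.60 to 7.61) with per-cell naming of the high-UMI set. T cell-like cells were 7.79% and 10.3%, with an interval from -0.139 to 5.45 points and a value of -0.365 points with per-cell naming, and neutrophil-like cells 4.18% and 2.02%, -2.16 points apart (-3.57 to -0.439). With at least 1000 UMIs per cell the neutrophil-like difference was -0.355 points (-1.63 to 1.34). Among T cell-like cells, regulatory T cell-like cells were 47.1% (57 of 121) in the WT and 22.95% (14 of 61) in the KO library, a difference of -24.2 points (-36.6 to -9.38). Their subcluster was named from 6 of its markers, but its leading genes included Cxcl2, H2-Ab1 and Cd74, genes better known from myeloid cells, so the name is uncertain. The interval held 0 with a mitochondrial limit of 10%, at -13.7 points (-27.9 to 2.30), and with 1000 UMIs in both libraries, at -4.76 points. CD8 T cell-like cells were 43.8% and 44.3%. Unnamed clusters were 11.7% of WT and 16.7% of KO cells, with median depths of 777 and 751 UMIs. Shares within the immune compartment are relative, so a lower share of macrophages raises the others. Of all 10903 WT and 7298 KO cells, 113 and 76 were dendritic cell-like, which is about the same share of each library. T cell-like cells, 121 and 61, were a smaller share of all KO than of all WT cells. NK cell-like cells, 51 and 57, were a larger one.

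**Figure D2:**
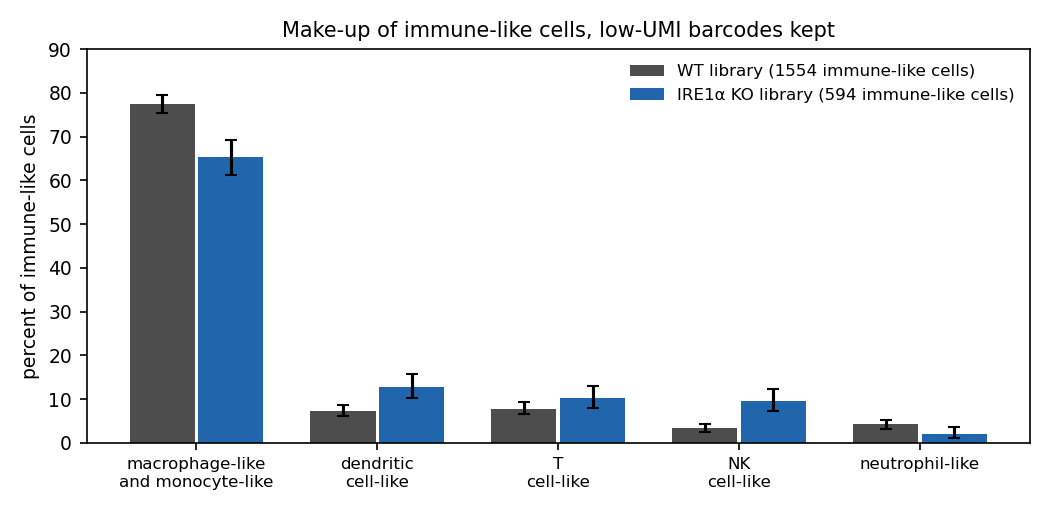
Percent of immune-like cells in each class with low-UMI barcodes kept, in the WT library (grey, 1554 cells) and the KO library (blue, 594 cells), with exact 95% binomial intervals for counting error only. Macrophage-like and monocyte-like cells were 77.5% and 65.3%, and NK cell-like cells 3.28% and 9.60%.

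T cell-like cells, 121 in the WT and 61 in the KO library, differed in make-up, so the ratios below mix the make-up of the class with the state of its cells. A dividing subcluster led by Mki67, which reached no subset name by its markers, held 11 WT and 20 KO of them, while the first clustering had 113 and 46 T cell-like and 59 and 72 NK cell-like cells against 51 and 57 here. The class therefore took in cells first clustered as NK cell-like, more of them from the KO library, and its mitotic genes go with the dividing subcluster. The exhaustion and checkpoint list had a median of -0.78 over 11 genes at percentile 0.010, with 7 lower and 0 higher by at least 1.5-fold. Pdcd1, which encodes the checkpoint receptor PD-1, was lower by 4.51-fold (2.37 to 10.3) at 56 and 10 UMIs and Rgs16 by 2.81-fold, with Cxcr6 and Bhlhe40 lower by 1.25-fold and 1.12-fold, both with intervals that held no difference. Naive and memory genes had a median of -0.70 over 7 genes at percentile 0.1, with the IL-7 receptor gene Il7r lower by 1.93-fold and Klf2 by 1.62-fold. The type I interferon list was at 0.63 over 25 genes, 14 higher and 0 lower, percentile 100. Usp18 was higher by 2.97-fold and Ifit2 by 2.82-fold, with 39.5% and 70.9% of KO UMIs in 1 cell, and Zbp1 and Irf7 were lower by 1.42-fold and 1.17-fold with intervals that held no difference. The interferon gamma list had a median of 0.17 over 13 genes at percentile 81.7, with Irgm1 higher by 1.72-fold. G2 and M phase genes were at 0.84 over 18 genes, percentile 100, with Mki67 higher by 2.46-fold and Ccnb2 by 2.07-fold, and S phase genes at 0.17 over 14 genes, percentile 75.5.

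Cytotoxic genes of the T cell-like cells had a median of 0.40 over 11 genes, 5 higher and 2 lower, percentile 99.3, and -0.43 with each cell named by its own marker score. Gzmb, a killing protease, was higher by 1.59-fold, and Ccl5 and Nkg7 were lower by 1.59-fold and 1.52-fold. Gzmc, with 56 UMIs in 2 KO cells and 0 in the WT library, was at least 22.3-fold higher, and near-identical granzyme genes can share its reads. The stress list was at -0.75 over 20 genes, percentile 0, with the heat shock gene Hspa1a lower by 4.44-fold and Ier3 by 4.19-fold, the second with 44.7% of WT UMIs in 1 cell. In NK cell-like cells, 51 and 57, the cytotoxic list had a median of 0.87 over 16 genes, 9 higher and 1 lower, percentile 100. Without the cell with most UMIs in each library it was 0.67. Ccl3 was higher by 2.65-fold with 56.9% of KO UMIs in 1 cell, Gzma lower by 1.76-fold and Eomes by 1.41-fold, the second with an interval that held no difference, and Gzmc higher by 19.8-fold with 95.7% of KO UMIs in 1 cell. Their type I interferon median was 0.04 over 9 genes at percentile 72.1, their interferon gamma median -0.25 over 3 genes, and their stress median -0.20 over 15 genes, with Fos lower by 1.68-fold. The exhaustion list measured 3 genes there, with a median of 1.34 and Tnfrsf9, the costimulatory receptor 4-1BB, higher by 2.53-fold with 35.6% of KO UMIs in 1 cell. Mki67 and Pdcd1 were also among the leading genes of subclusters of the T cell-like class, so its make-up can add to their ratios. Ratios within subclusters were not compared, so how much it adds was not tested. Free RNA was 23.9% and 22.9% of UMIs in T cell-like and 26.6% and 24.5% in NK cell-like cells, and sums were small, 200561 and 167937 UMIs for T cell-like cells and 75923 and 118753 for NK cell-like cells.

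Endothelial cell-like and fibroblast-like cells of the KO library also had higher interferon-stimulated genes. In endothelial cell-like cells of the low-UMI set, 85 and 42, 24 of 25 type I interferon genes were at least 1.5-fold higher, with a median of 1.51 at percentile 100. Ifit2, which inhibits translation of viral RNA, was higher by 7.56-fold (4.36 to 14.7) and Oasl2 by 5.51-fold. Among members with at least 50 UMIs the smallest ratios were 1.52-fold for Rtp4 and 1.55-fold for Eif2ak2, the second with an interval that held no difference. Without the cell with most UMIs in each library the median was 1.08. Interferon gamma genes were at 1.34 over 7 genes, with the guanylate-binding proteins Gbp3 and Gbp7 higher by 6.72-fold and 2.88-fold, and the list of endothelial activation and angiogenesis at -0.01 over 18 genes, percentile 65.7. Aplnr, the apelin receptor, was lower by 3.31-fold and Plvap, of endothelial fenestrae, by 1.61-fold, and the growth factors Pgf and Angpt2 were higher by 1.43-fold and 1.38-fold, with 50.8% and 46.2% of KO UMIs in 1 cell and the second with an interval that held no difference. Their stress list was at -0.27 over 15 genes.

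Fibroblast-like cells, 242 and 49 in the low-UMI set, had a type I interferon median of 0.59 over 30 genes, 15 higher and 1 lower, percentile 100, with Ifi44 higher by 2.33-fold and Ifi27l2a by 2.01-fold. Interferon gamma genes were at -0.04 over 14 genes, and Cxcl10 was lower by 6.09-fold at 55 and 2 UMIs, with 54.5% of the former in 1 cell. The extracellular matrix list had a median of 0.18 over 29 genes at percentile 99.9. Lox and Loxl2, which cross-link collagen, were higher by 1.87-fold and 1.49-fold, and the stromelysin Mmp3 and the proteoglycan Lum lower by 9.18-fold (4.49 to 27.3) and 2.61-fold. Chemokine genes were at -0.27 over 18 genes, 8 lower and 1 higher, percentile 2.87, with the monocyte chemokine Ccl2 lower by 4.64-fold (3.03 to 7.87) and Il6 by 4.36-fold, and Mif higher by 1.54-fold. Their stress list was at -0.28 over 20 genes, with Nr4a1 lower by 4.17-fold. In the high-UMI set, with 128 and 30 cells, the interferon, matrix and chemokine medians were 0.44, 0.20 and -0.26. The larger of the 2 fibroblast-like clusters of the low-UMI set was led by genes that included Rgs5 and Acta2, genes of mural cells around vessels. Free RNA was 17.1% of WT and 10.7% of KO UMIs in the low-UMI set. In the high-UMI set it was 24.4% and 11.2%, so free RNA can bear on the ratios there.

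**Figure D3:**
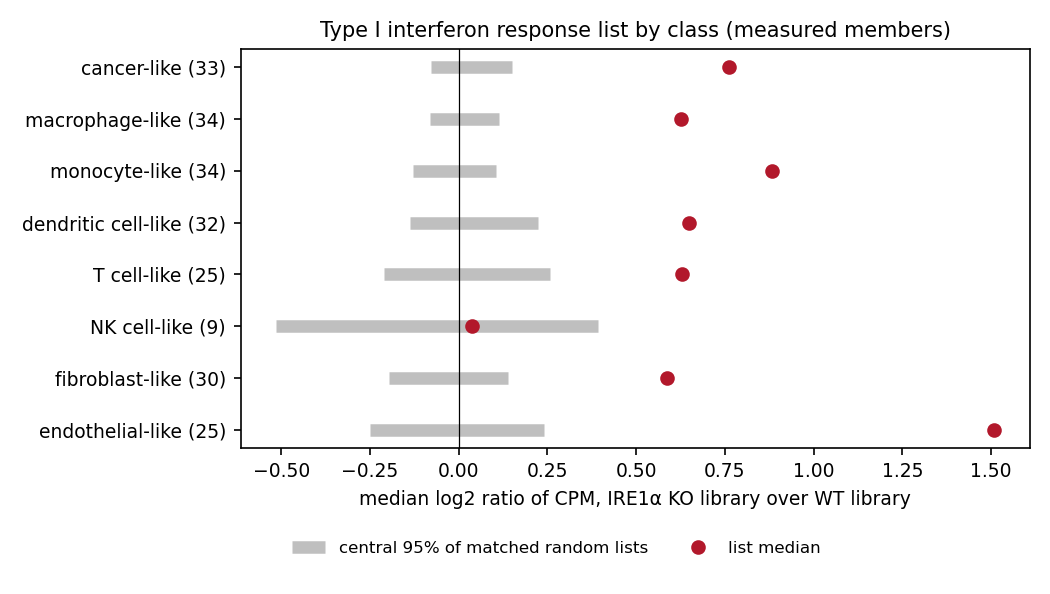
Median log2 ratio of CPM, KO library over WT library, of the type I interferon list in each cell class (red points), with the central 95% of matched random lists (grey bars) and measured members in parentheses. Cancer-like and macrophage-like cells are from the high-UMI set and the other classes from the low-UMI set, and medians run from 0.04 in NK cell-like to 1.51 in endothelial cell-like cells.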

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

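The tests given here, on single clusters, on removal of clusters held almost only by the WT library, on subtraction of free RNA, on 7589 UMIs in both libraries and on the number of clones and pools, were chosen after the data were seen. A minimum of 1000 UMIs was an alternative fixed in advance, but its use as a test was chosen after its value was seen. A signal outside the comparisons of the report came from an unnamed cluster of 29 cells in the low-UMI set, 6 from the WT and 23 from the KO library. Its leading genes were those of mast cells and basophils, Tpsab1, Tpsb2, Cma1, Cpa3 and Mcpt8.

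The XBP1s and ER-associated degradation list was lower in KO cancer-like cells, with a median log2 ratio of -0.74. Cancer-like clusters held almost only by the WT library could carry such a difference, but it was present in each of the 10 cancer-like clusters with at least 50 cells of both libraries. The highest cluster median, -0.28, lay below the lower end of the random lists of the whole class, -0.07. No random lists were drawn within clusters, where counts are fewer and the range can be wider. A difference between the knockout line and its parent other than the edit cannot be told apart from the edit, because 1 knockout line was sequenced. A lower output of XBP1s targets without IRE1α is the biological hypothesis that the design names, and it stays open beside a clonal difference.

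The type I interferon list was higher in KO cancer-like cells, with a median of 0.76, and in KO macrophage-like cells, with a median of 0.63. Free RNA from cells rich in interferon-stimulated genes could give both, yet after its subtraction the medians were 0.79 and 0.65. Both lay above the upper ends of the random lists drawn before subtraction, 0.15 and 0.11. Removing the clusters held almost only by the WT library left 0.63 in cancer-like cells, which argues against them as the whole cause. Over 10 clusters all medians were above 0, and the highest was 0.98. The medians of cluster 5, 0.017, and cluster 2, 0.125, lay inside the range of random lists of the whole class. Cluster 2 held 272 WT and 971 KO cells, more KO cells than any other cancer-like cluster. The rise was therefore not shown in every cluster, and a contribution of the make-up of clusters stays open. Whether the difference came with the edit, with the clone or with these pools was not tested.

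The share of immune-like cells was lower in the KO library, a difference of -2.54 percentage points at minimums that differed between libraries. A higher minimum in the KO library may have added to this, since with 7589 UMIs in both the difference was -0.616 points. With 1000 UMIs in both the difference was -4.22 points with an interval below 0, but that comparison does not isolate the minimum. Shallow barcodes named cancer-like then entered unevenly, among them a cluster with a median of 1308 UMIs and 626 WT and 3672 KO cells. Such barcodes enlarge the KO denominator, so how much of the difference the minimum accounts for was not settled. A different yield of cell types from the dissociated pools cannot be told apart from a difference between tumours, because each group had 1 pool. A lower immune share in tumours of the KO line stays open as the biological hypothesis.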

How the results depend on the processing

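Of the alternatives here, the low-UMI set and those within it, the higher minimum for both libraries, free RNA subtraction, removal of clusters held almost only by the WT library and removal of the cell with most UMIs were chosen after seeing the data. Over 22 comparison results and 207 values under alternatives, 174 were the same, 30 moved and 3 reversed. A share or gene was said to move when it left the counting interval of the main value. A list median was said to move when its shift exceeded a limit set by the width of the range of its random lists. For 134 named genes, 952 of 1164 values were the same, 202 moved and 10 reversed, and thinning moved more of them than any other alternative. For 18 lists of the low-UMI set, 119 of 143 values were the same, 19 moved and 5 reversed. The XBP1s list of cancer-like cells stayed between -0.77 and -0.69 and the type I interferon list between 0.63 and 0.82. Shares below are differences in percentage points, lists and genes log2 ratios, and the cause of a change was not tested unless given. With 1000 UMIs in both libraries, where smaller cells enter by construction, the immune-like share was -4.22, the fibroblast-like share -1.75, the macrophage- and monocyte-like share of immune-like cells -6.32, the regulatory share of T cell-like cells -4.76, tumour-associated macrophage genes -0.27 and Cxcl9 of macrophage-like cells -0.56. With the higher minimum for both, which removes WT cells only, immune-like and fibroblast-like shares were -0.616 and -0.753. With low-UMI cells kept, the immune-like share was -6.11, and in macrophage-like cells the type I interferon list was 0.50, Ccl24 -2.45, Cd209d 0.03, Cxcl9 -1.12 and Hspa1b -0.25, and the cause was not tested. With the minimum at 10% of the 99th percentile the macrophage interferon list was 0.53, and with no doublet removal the macrophage MHC class II list was 0.17. With each cell named by its own score, the macrophage- and monocyte-like share was -7.46, NK cell-like 1.34, dendritic cell-like 1.77, tumour-associated macrophage genes 0.012 and Ccl24 -2.93. At resolution 2 the macrophage- and monocyte-like share was -4.78, with an interval that held 0, and the fibroblast-like share -0.521. Thinning to 1000 UMIs gave 0.36 for Ern1, 0.071 for interferon gamma genes of cancer-like cells, 0.83 for interferon genes of macrophage-like cells, 1.24 for Col6a1, -0.18 for Mcm6, 0.03 for Ankrd37 and -0.71 for Cxcl9. Thinning kept a small part of the UMIs and its gene values have no interval, so those of genes with few UMIs are uncertain. With members of at least 100 UMIs, so fewer genes, the interferon gamma list of cancer-like cells was 0.016. Without clusters held almost only by the WT library, Ern1 was 0.17 and the interferon list 0.63 in cancer-like cells. Within the low-UMI set, per-cell naming gave -4.94 for immune-like, -2.03 for fibroblast-like, -18.0 for macrophage- and monocyte-like, -0.365 for T cell-like, 3.78 for NK cell-like and 12.2 for dendritic cell-like shares, -0.43 for the T cell-like cytotoxic list and 0.21 for the inflammatory macrophage list. Resolution 0.5 there gave -7.22 for macrophage- and monocyte-like and 1.79 for dendritic cell-like shares and 0.17 for the inflammatory list, and resolution 2 gave -2.17 for fibroblast-like cells. A mitochondrial limit of 10% gave -0.12 for the cytotoxic and 0.022 for the inflammatory list, and 1000 UMIs gave -0.355 for neutrophil-like cells. No value came from alternatives that named no such cells, or macrophage-like cells alone. For shares of immune-like classes these were the 99th percentile minimum, the mitochondrial limit, no doublet removal and resolution 0.5 of the high-UMI set, and also 1000 UMIs for neutrophil- and dendritic cell-like and per-cell naming for neutrophil-like cells. Per-cell naming of the high-UMI set and names of the first clustering gave none for regulatory and CD8 T cells, resolution 2 gave none for lymphocytes and neutrophils, and resolution 0.5 of the low-UMI set none for the dendritic cell-like interferon list. No paired analysis was possible because each group was 1 library and no result came from a test across samples. Depth limits detection in small cells, since macrophage-like cells of the high-UMI set had a median of 7930 UMIs in the WT library against 21889.5 in cancer-like cells, so genes with few UMIs in lymphocytes, neutrophils and monocytes could be measured only in part.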

Other observations

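All comparisons in this part were chosen after the data were seen. Dendritic cell-like and monocyte-like cells of the low-UMI set, for which no list had been planned, also carried higher interferon genes in the KO library. In monocyte-like cells, 270 and 162, the type I interferon list had a median of 0.88 over 34 genes, 28 at least 1.5-fold higher and 0 lower, percentile 100. Ifi44 was higher by 3.56-fold (2.10 to 6.57) and Oas3 by 3.09-fold. Among members with at least 50 UMIs the smallest ratios were 1.16-fold for Oas1a and 1.31-fold for the kinase Eif2ak2, both with intervals that held no difference. The interferon gamma list was at 0.47 over 18 genes, percentile 100, with the GTPases Irgm2 and Gbp2 higher by 3.13-fold and 1.93-fold and Ciita, the activator of MHC class II, lower by 1.47-fold with an interval that held no difference. MHC class I genes had a median of 0.35 over 17 genes, percentile 100, led by the peptide transporter Tap1 at 1.79-fold and H2-T23 at 1.60-fold, whereas MHC class II genes were at -0.15 over 8 genes, percentile 11.2. The stress list was at -0.18 over 20 genes, with Nr4a1 lower by 1.62-fold.

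Dendritic cell-like cells, 113 and 76, were mostly of the cross-presenting cDC1 type by their markers, with smaller mature and plasmacytoid groups. The cluster named plasmacytoid, 32 and 18 cells, was led by the plasma cell genes Igha, Jchain and Mzb1 beside Siglech and Ly6d. At resolution 2 it split into 18 and 9 plasma cell-like and 14 and 9 plasmacytoid cells, so the class took in plasma cells, and its share of immune-like cells then differed by 5.93 points. The cDC1 cluster held the cDC2 gene Mgl2. Their type I interferon list had a median of 0.65 over 32 genes, 19 higher and 0 lower, percentile 100. Rsad2, the antiviral enzyme viperin, was higher by 6.02-fold (3.06 to 14.6) at 9 and 49 UMIs, with 42.9% of KO UMIs in 1 cell, and Mx1 by 2.48-fold. Interferon gamma genes were at 0.63 over 12 genes, 7 higher and 1 lower, percentile 100, with Irgm1 and Ciita higher by 1.99-fold and 1.87-fold and Cxcl10 lower by 1.62-fold with 51.6% of WT UMIs in 1 cell. The MHC class I median was 0.22 over 17 genes, percentile 97.6, with H2-T23 higher by 1.95-fold and Tap1 by 1.68-fold, and the MHC class II median 0.12 over 10 genes, percentile 81.3. Fosb, an immediate early gene of dissociation, was lower by 2.87-fold, and the stress list was at -0.47 over 20 genes. Free RNA was 11.3% of WT and 15.2% of KO UMIs in monocyte-like cells and 15.6% and 12.8% in dendritic cell-like cells.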
